A study of Mus musculus with 2 samples.

How the data were processed

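ATAC-seq was carried out on heart tissue of mouse embryos at embryonic day 13.5. In this assay a transposase inserts sequencing adapters into accessible DNA, and regions where many insertions pile up are called as peaks. The samples formed 1 group of 2 biological replicates, each labelled as tissue pooled from male and female embryos. The replicate numbers are those given by the labels. The labels name separate biosamples, and nothing in them says how many embryos each held.

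The files analysed were peak lists on the mouse assembly mm10, per the file headers. The reads themselves were not used here, so the sequencing depth of both libraries is unknown and no value below carries an interval for depth. The aligner, the peak caller and their versions are not given in the sources used here, nor is any shift of the reads for the transposase. For each replicate the authors deposited a list thresholded on the irreproducible discovery rate (IDR), a longer list named for pseudoreplicates, and a list named as IDR-ranked. These were deposited with each replicate by itself, and 4 further lists used here were deposited for the whole series. The signal column of the deposited lists holds 1 value per summit, and its scale is not given in the sources used here. The −log10 p column of the deposited lists holds the peak caller's own value per summit. The score column of the deposited IDR-thresholded lists reached no lower than 540, which corresponds to an IDR of 0.0501 on the relation between score and IDR found in the ranked lists. Per the file headers, the thresholded and pseudoreplicated lists also derive from a further file whose content is not stated. The thresholded lists held 21 chromosomes. They lacked 165 summit rows of replicate 1 and 187 of replicate 2 that reached the same score in the ranked lists. Signal and −log10 p values are the authors' own per-peak values and served to rank and describe peaks. Ratios of them between replicates describe these lists and not amounts of accessible DNA. Of the whole-series lists, 2 ranked lists were not used because their columns could not be tied to a replicate.

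Overlapping rows of a list were joined into regions, and a region took the signal and the summit of its strongest row. A region was shared when a region of the other replicate covered at least 50% of the shorter of the pair. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. For chance overlap, the regions of replicate 2 were moved at random within their chromosomes 100 times. Across shared regions, Pearson's r and Spearman's rho of log2 signal were taken without a p-value, because peaks and genes are not independent replicates.

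Annotation came from GENCODE mouse release M21 on GRCm38 patch 6, the assembly that mm10 names, with 21938 protein-coding genes on 21 chromosomes. A summit within 1000 bp of a transcription start site (TSS) of a protein-coding gene was classed as promoter, and other summits as exon, intron or intergenic. A gene had an open promoter when a region overlapped 500 bp either side of a TSS of any of its annotated transcripts. Unless another list is named, this refers to the thresholded lists. A gene without an open promoter may therefore still be listed in the longer ones. Distal regions had their summit over 1000 bp from every such TSS and were assigned to the gene of the nearest TSS within 100 kb.

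There were 16 gene lists, of which 15 were written out by symbol and 1 held all olfactory receptor genes. They covered cardiac transcription factors, sarcomere, cardiac ion handling and natriuretic peptides, endothelium and endocardium, epicardium, fibroblast and valve mesenchyme, smooth muscle and pericyte, erythroid, macrophage and leukocyte, neural, liver, skeletal muscle, lung and foregut epithelium, cell cycle and ubiquitous genes. The erythroid gene Ahsp was not in the annotation. Each list was ranked in each replicate among 10000 random lists of equal size, matched on decile of promoter CpG content (observed over expected) for promoters and on decile of assignable territory for distal regions. A list was called high or low when it lay above or below at least 9900 of the random lists in both replicates. Such ranks describe these libraries and are not a test over animals. Named members of a list were up to 6 with the most assigned distal regions and up to 4 without a promoter region in either replicate. Across all genes, the 10 genes with the most distal regions, the 5 strongest promoter regions, the 10 strongest distal regions, the strongest shared distal region of each of 7 lists for cells of the heart, and the 3 strongest regions found in 1 replicate only were named. Of the 7 lists, the epicardial one had no shared distal region to name. Other members were named after their values were seen, to show which genes a count held.

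For motifs, 20 consensus sequences were searched on both strands within 75 bp of each distal summit, in replicate 1 at 3577 summits and in replicate 2 at 2360. The share with a match was divided by the share of flanking windows 1000 bp away that lay in no region of the list. The ratio carries a 95% interval from 1000 bootstrap draws over chromosomes, and a motif was called when the interval excluded 1 in both replicates. Short consensus sequences name a family of factors only. The lists, motifs, named-gene rule, calls and all alternatives except 2 were fixed before the data were examined. Each choice was changed in turn, among them the list, the threshold, the overlap rule, the windows, the matching and the replicate. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

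The procedures were tested on simulated data. With 50% of the 11422 regions of replicate 1 planted in a second list, 50.1% were found. Planted regions kept their width and were moved too little to miss the overlap rule. This count therefore checked the computation only and says nothing about lists that differ in width or signal. Of 200 simulated lists of 20 genes with no difference, 1 was called high and 0 were called low. Of 200 lists whose members had 3 times the odds of being open, 8 were called high, and 122 were called with 10 times the odds. In this setting lists of this size showed large differences only. The simulated replicates were drawn independently given CpG content. The real ones were not independent, as 8016 of the 9488 genes open in replicate 1 were open in both. These counts therefore do not give the rate of false or missed calls in the real lists. With no motif planted, 0 of 20 pairs of replicates were called higher or lower. Simulated summits and flanks had the same random base composition, so false calls from a difference in composition could not show. With a motif planted in 5% of 2000 summits, 5 of 5 pairs were called, at a mean ratio of 3.82 against 3.81 planted. Both ratios used the same flank counts, so their closeness was largely built in.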

Results

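Open chromatin of the mouse heart at embryonic day 13.5, a stage at which the chambers have formed and the myocardium is still growing, was profiled in 2 biological replicates. The thresholded list of replicate 1 held 11422 regions covering 8.42 Mb, and that of replicate 2 held 10150 regions covering 6.21 Mb. Median region width was 721 bp in replicate 1 and 594 bp in replicate 2. Only 1 tissue and 1 stage were among the samples, so the comparisons are between the replicates, and between genes, gene groups and regions within each. Read counts were not part of the lists, and the depth behind each value is therefore unknown.

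The question of the first comparison was how far the replicates gave the same open regions. The strongest promoter regions of both replicates lay at Dck, which encodes deoxycytidine kinase, and at Cfdp1, Hibch, Tmem126b and Rcl1. Their signal was 20.1 ± 2.34 at Dck, 20.1 ± 0.560 at Cfdp1, 19.4 ± 3.49 at Hibch, 19.5 ± 4.15 at Tmem126b and 19.1 ± 2.62 at Rcl1 (SD, n = 2 for each). The Dck region spanned positions 88764749 to 88765488 of chromosome 5, the Cfdp1 region 111853866 to 111854564 of chromosome 8, and the Hibch region 52844671 to 52845279 of chromosome 1. Of the regions of replicate 1, 72.7% (8307 of 11422; exact Clopper-Pearson 95% interval 71.9 to 73.5%) had a counterpart in replicate 2. Of the regions of replicate 2, 85.4% (8667 of 10150; interval 84.7 to 86.1%) had a counterpart in replicate 1. With the regions of replicate 2 moved at random, 0.345% of replicate 1 regions and 0.387% of replicate 2 regions had a counterpart on average. The share depended on the list, since in the longer pseudoreplicated lists 42.5% of replicate 1 and 59.0% of replicate 2 regions were shared.

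The strongest regions listed in replicate 1 only were the promoters of Polr3h (signal 15.8) and Hat1 (15.3), which encode an RNA polymerase III subunit and a histone acetyltransferase, and an intron of Zfp286 (15.7). In replicate 2 only, they lay 7201 bp from Gm17019 (signal 11.1), in an intron of Nkain3 (10.8), and 751 bp from the TSS of Med13 (10.0), a Mediator kinase module gene. Of these 6 regions 4, at Hat1, Zfp286, Nkain3 and Med13, overlapped the other replicate's longer pseudoreplicated list. Regions not shared were weaker than shared ones. Their median signal was 6.94 against 10.7 in replicate 1 and 4.81 against 7.87 in replicate 2. Across 8258 shared regions, log2 signal correlated at r = 0.760 and rho = 0.767. The median ratio of signal in replicate 2 to replicate 1 was 0.769, and 90.2% of shared regions had the lower value in replicate 2. The −log10 p values had a median ratio of 0.457.

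**Figure D1:**
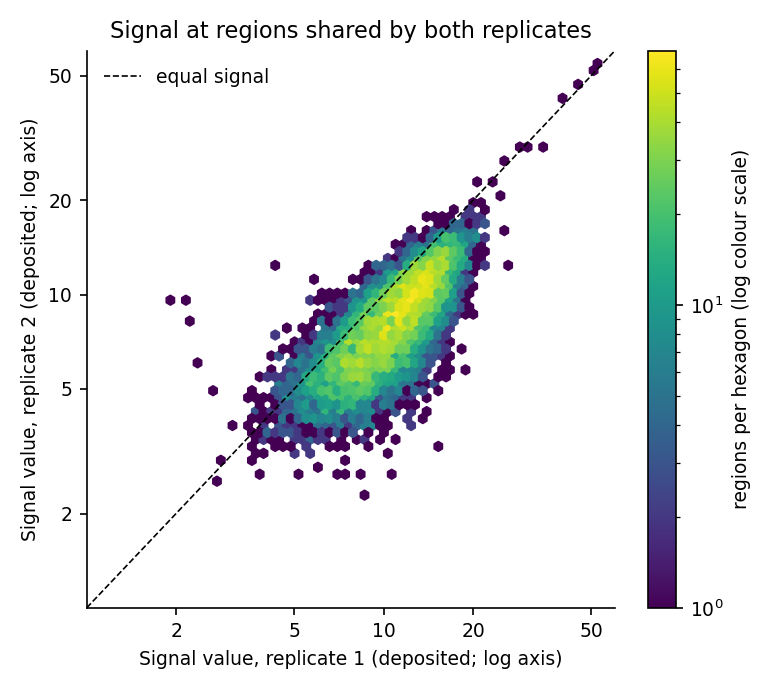
Signal value of each of the 8258 regions shared by both replicates, replicate 1 on the horizontal and replicate 2 on the vertical axis, both as deposited and on log axes, with colour for the number of regions per hexagon. Most regions lie below the dashed line of equal signal (90.2% lower in replicate 2), while a few strong regions with signal above 20 lie close to it.

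The second comparison asked where in the genome open regions lay. Promoters of protein-coding genes held 84.7% ± 1.38 of summits (SD, n = 2), while promoter windows make up 3.59% of the genome. Introns held 6.47% ± 1.03, intergenic sequence 7.19% ± 0.370 and exons 1.66% ± 0.0267 (SD, n = 2 for each). A promoter region was present at 9488 genes (43.2%) in replicate 1 and 8536 genes (38.9%) in replicate 2, and at 8016 genes in both. Promoter regions were shared more often than others, but they were also stronger and wider. In replicate 1 their median signal was 10.2, against 7.05 for intron and 7.65 for intergenic regions. Their median width there was 776 bp, against 497 and 524 bp. Sharing was not compared between classes at like signal or width. In replicate 1, 81.0% of promoter regions (interval 80.1 to 81.8%) had a counterpart in replicate 2, against 32.6% of intron (29.8 to 35.4%) and 49.1% of intergenic regions (46.2 to 52.1%). In replicate 2 the shares were 90.9% (90.3 to 91.5%) for promoter, 50.5% (46.9 to 54.2%) for intron and 65.2% (61.8 to 68.4%) for intergenic regions. In the pseudoreplicated lists 57.1% of summits lay at promoters.

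The genes with the most distal regions were Chd2, a chromatin remodeller (5 regions in each replicate), and Zfp36l2, an RNA-binding protein gene (6 and 4). Tex14 and Arhgap23 had 4 in replicate 1 and 5 in replicate 2. Shf, Marcks and Kcnrg had 4 in each replicate, Prrc2b 5 and 3, Smad6, an inhibitor of BMP signalling, 6 and 2, and Gm21119 2 and 6. The strongest distal regions of both replicates lay between genes or in predicted transcripts. The strongest was on chromosome X from 143482940 to 143483180, 35531 bp from Pak3, with a signal of 53.5 ± 1.54 (SD, n = 2). The next lay on chromosome 2 from 69355470 to 69355735, 12987 bp from Abcb11 (51.2 ± 1.84), and on chromosome 10 from 96077546 to 96077951, 58941 bp from Gm5426 (46.3 ± 1.50). The others were nearest to G6pd2 (42.0 ± 1.50), Frmd4a (31.7 ± 2.94), Tyrp1 (29.6 ± 0.247), Galc (29.2 ± 0.0373), Nxph1 (25.8 ± 1.50), Ccnh (23.0 ± 0.335) and Myl12b (22.8 ± 3.35), at 12233 to 1765843 bp. Of these 10 regions, 7 had 45.4 to 70.5% of their 16-base words in the mitochondrial genome, so their signal need not be open chromatin. The median share of 31-base words found elsewhere on the chromosomes was 32.6% over the 10.

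The third comparison asked which groups of genes had open promoters. Genes of the contractile apparatus differed between the replicates. In replicate 1, 15 of 24 sarcomere genes had an open promoter, more than in 10000 of 10000 matched random lists, and in replicate 2 only 4 had, more than in 1994. The 11 genes open in replicate 1 only were Actc1, Csrp3, Des, Ldb3, Myh7, Myl2, Myl3, Tnni1, Tnni3, Tnnt2 and Ttn, among them cardiac actin, β-myosin heavy chain, the cardiac troponins T and I and titin. Open in both were Actn2, Tpm1, Myl4 and Myom1, with signals of 7.50 and 4.45 at Actn2. The Myl4 and Myom1 regions also lay at a TSS of Cdc27 and of Myl12a and Myl12b, so that without regions shared with another gene 13 sarcomere genes were open in replicate 1 and 2 in replicate 2. Mybpc3, Myh6, Myl7 and Myom2 were among 9 without a promoter region in either replicate. In the pseudoreplicated lists Mybpc3 (3.65) and Myh6 (2.96) were listed in replicate 1 only, and Myl7 and Myom2 in neither. The sarcomere list was not called, and 1 replicate decided its value. It stood at 2.71 times the random mean in replicate 1 and 0.840 times in replicate 2. Against random lists not matched on CpG content the mean ratio of both replicates turned from 1.77 to 0.935, and in the conservative list deposited for the whole series it was 1.18.

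Genes of ion handling and natriuretic peptides were open in 12 of 18 cases in replicate 1 (above 9762 of 10000 random lists) and 7 in replicate 2 (above 2024), and the list was not called. Atp2a2, the sarcoplasmic calcium pump (signals 9.57 and 7.87), Ryr2, the calcium release channel (7.66 and 3.69), Jph2 (6.46 and 4.99) and Gja5 (6.64 and 7.25) were open in both, though the Gja5 region also lay at Gpr89. Slc8a1 (11.3) and Kcnh2 (5.50) were listed in replicate 1 only. Casq2, Gja1, Hcn1 and Kcnq1 had no promoter region. Hcn1 was listed in both pseudoreplicated lists (6.28 and 2.67), Casq2 in replicate 1 only (3.74), and Gja1 and Kcnq1 in neither. Of 24 cardiac transcription factor genes, 17 were open in replicate 1 and 13 in replicate 2, 62.5% ± 11.8 (SD, n = 2) against 60.3% in random lists of like CpG content, which was no call. Mef2d (7.30 and 5.35), Tead1 (7.08 and 6.68), Myocd, a coactivator of muscle genes (7.07 and 6.23), Gata6 (5.86 and 5.93) and Mef2c (6.96 and 3.99) were open in both replicates, and Gata5 in replicate 1 only (7.85). Hand1, Hand2, Irx4 and Prdm16 had no promoter region. In the pseudoreplicated lists Hand2 (5.05) was listed in replicate 1 only, Prdm16 (2.74) in replicate 2 only, and Hand1 and Irx4 in neither. The ratio of the ion handling list turned from 1.14 to 0.689 in the top 50% of rows by −log10 q and to 0.732 in the conservative list.

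Erythroid genes had open promoters far more often than random lists of like CpG content. Of 19 genes, 10 were open in replicate 1 and 8 in replicate 2, 5.35 ± 0.0927 times the CpG-matched mean (SD, n = 2) and above 10000 of 10000 random lists in both, so the list was called high. The α-globin genes Hba-a1 and Hba-a2, Tal1, Slc4a1, Nfe2 and Epb42 were open in both. Signals were 5.97 and 5.56 at Tal1, a blood cell transcription factor, and 8.50 and 6.44 at Slc4a1, the red cell anion exchanger. Spta1 (8.85) and Hbb-y, an embryonic globin gene (5.38), were listed in replicate 1 only. Alas2, Gata1, Gypa and Hba-x had no promoter region. Gata1 was listed in both pseudoreplicated lists (4.56 and 4.58), Alas2 (3.16) and Gypa (5.95) in replicate 1 only and Hba-x in neither. Against random lists not matched on CpG content the ratio was 1.15 and the call was lost.

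Among the lists for other cell types of the heart, epicardial genes were called low at promoters, and endothelial, fibroblast and smooth muscle genes were not called. Of 21 endothelial and endocardial genes 3 were open in each replicate, Kdr and Tie1 in both, 0.397 ± 0.0330 times random (SD, n = 2). That lay below 9978 random lists in replicate 1 and 9854 in replicate 2, which missed the call. Cdh5, Egfl7, Emcn and Eng were not open. Of these, Cdh5 (4.59 and 2.88) and Egfl7 (3.23 and 2.99) were listed in both pseudoreplicated lists, Eng in replicate 1 only (2.94) and Emcn in neither. Of 17 fibroblast and valve genes 3 were open in each, Fn1 and Snai1 in both, below 9901 and 9695 random lists, which was not called either. The collagen genes Col1a1, Col1a2 and Col3a1 and Dcn were not open. Col1a2 was listed in both pseudoreplicated lists (6.32 and 3.05), Col1a1 in replicate 1 only (4.20), and Col3a1 and Dcn in neither. Epicardial genes were called low, with 1 of 12 (Tbx18) in replicate 1 and 0 in replicate 2, below 9991 and 9998 random lists. Aldh1a1, Aldh1a2, Bnc1 and Krt19 were not open. Of these, Aldh1a2 (5.49), Bnc1 (3.48) and Krt19 (2.95) were listed in the pseudoreplicated list of replicate 1 only, and Aldh1a1 in neither. Of 10 smooth muscle and pericyte genes 3 were open in replicate 1 and 1 in replicate 2, Smtn in both (6.48 and 6.87), 20% against 21.3% in random lists, at 1.29 times random in replicate 1 and 0.520 in replicate 2. With promoter windows at outermost 5′ ends only, the smooth muscle ratio fell from 0.904 to 0.240, without a call. Abcc9, Kcnj8, Myh11 and Notch3 had no promoter region. In the pseudoreplicated lists Kcnj8 (4.08) and Myh11 (4.92) were listed in replicate 1 only, and Abcc9 (4.45) and Notch3 (3.91) in replicate 2 only. In the pseudoreplicated lists the epicardial call was lost through replicate 1, with 8 of 12 genes (1.21 times random) there and 0 in replicate 2, a mean of 0.603. Endothelial genes turned there from 0.397 to 1.24 times, fibroblast genes from 0.437 to 1.03 (1.19 in replicate 1 and 0.860 in replicate 2) and smooth muscle genes from 0.904 to 1.37 (1.68 and 1.06), none of them called. In the top 50% of rows by −log10 q endothelial genes were called low, at 0.145 times.

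Genes of tissues outside the heart mostly had no promoter region. Neural genes were called low, with 1 of 19 (Elavl4) in replicate 1 and 0 in replicate 2, below 10000 random lists in both, and Ascl1, Dlx2, Emx2 and Eomes had no region. Dlx2 was listed in both pseudoreplicated lists (3.50 and 3.99), Emx2 (4.36) and Eomes (3.74) in replicate 1 only and Ascl1 in neither. Lung and foregut genes were called low, with Foxj1 open among 14 in both replicates, below 9999 and 9990 random lists. Cdh1, Epcam, Foxa1 and Foxa2 had no region. In the pseudoreplicated lists Epcam (4.20) and Foxa1 (3.43) were listed in replicate 2 only, and Cdh1 and Foxa2 in neither. Olfactory receptor genes were called low, with Olfr575 open among 1135, below 10000 and 9999 random lists. That call was lost in the top 50% of rows by −log10 q, at 0.129 times random. Of 20 liver genes Foxa3 was listed in both replicates, at a region that also lay at Sympk, and Afp, Ahsg, Alb and Apoa1 were not. Of 19 skeletal muscle genes 3 were listed in replicate 1 and 2 in replicate 2, all at regions that also lay at another gene. Acta1, Cacna1s, Myf5 and Myf6 were not, though Acta1 was in the pseudoreplicated list of replicate 1 (3.56). Of 16 macrophage and leukocyte genes only Fcgr3 was open (4.91 and 3.34), and Aif1, C1qa, C1qb and C1qc were not. These 3 lists were not called, and their CpG-matched random means were 7.01% for liver, 19.4% for skeletal muscle and 8.73% for macrophage genes. Cell cycle genes were open in 20 of 22 cases in each replicate, among them Mki67 (12.2 and 9.92) and Cenpf (15.8 and 13.7), above 9689 and 9943 random lists. Ubiquitous genes were open in 19 and 17 of 20 cases, among them Actb (9.12 and 9.66), Hprt (13.4 and 7.25) and Ywhaz (10.2 and 7.22), above 9949 and 9738. Neither list reached the call in both replicates. Against random lists not matched on CpG content, macrophage (0.153 times) and liver promoters (0.122) were called low and cell cycle (2.22) and ubiquitous ones (2.19) high. In the pseudoreplicated lists neural, lung and foregut, and olfactory receptor genes stood at 0.336, 0.332 and 0.294 times random and were still called low, the last with 5 genes in replicate 1 (0.0907 times) and 18 in replicate 2 (0.498).

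**Figure D2:**
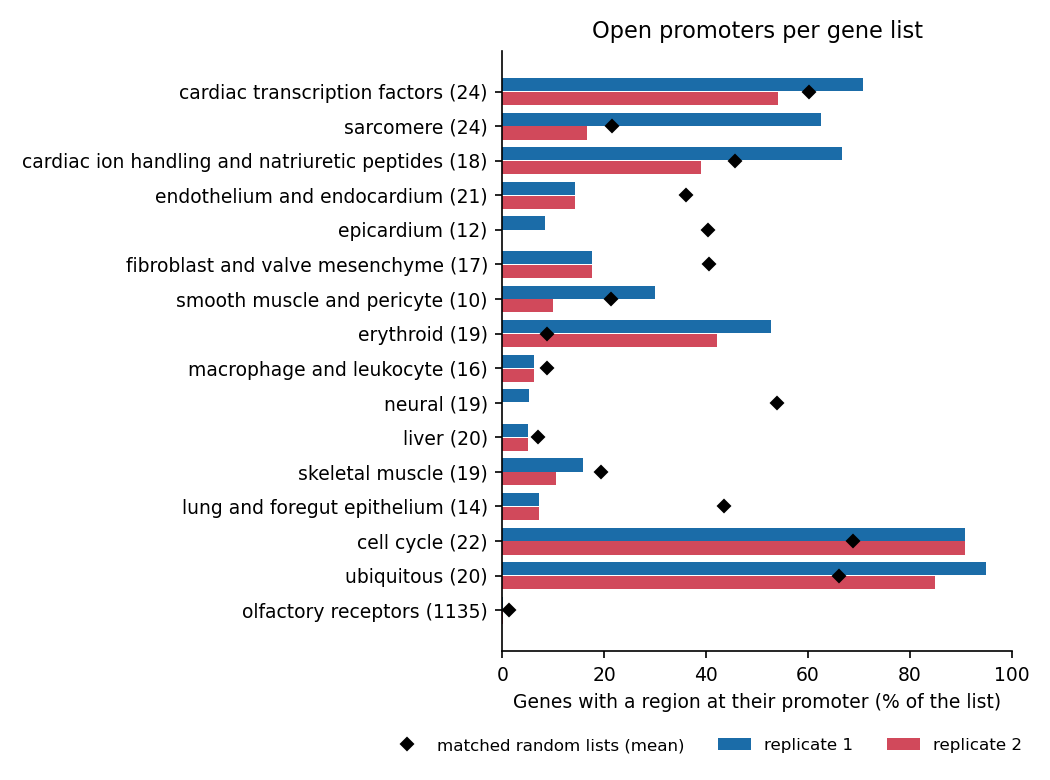
Percentage of genes with a region at their promoter for 16 gene lists (list sizes in brackets), as bars for replicate 1 and replicate 2, with diamonds for the mean of CpG-matched random lists. Sarcomere genes stand at 15 of 24 in replicate 1 and 4 of 24 in replicate 2, while erythroid genes stand above their random mean in both.

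**Figure D3:**
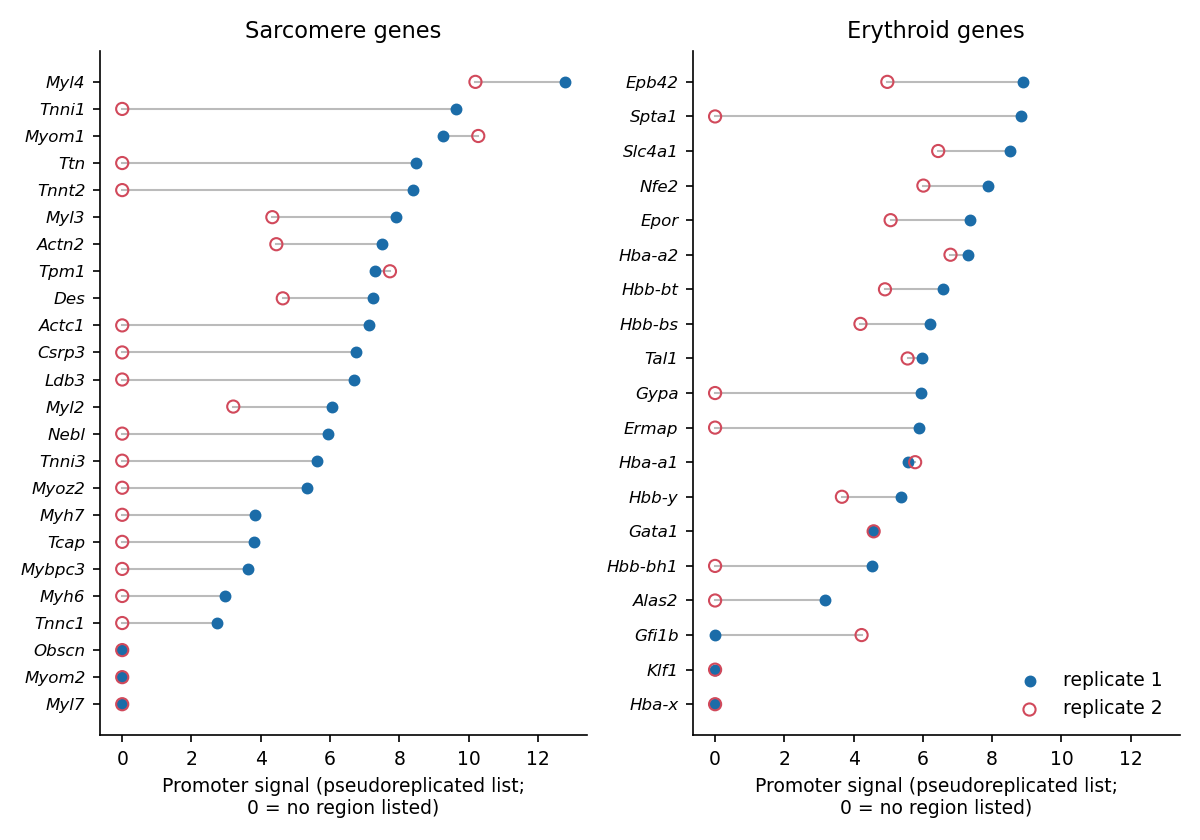
Promoter signal as deposited (horizontal axis) of each sarcomere gene and each erythroid gene in the longer pseudoreplicated lists, filled points for replicate 1 and open circles for replicate 2, with 0 for genes without a listed region. In these lists 21 sarcomere genes were listed in replicate 1 and 7 in replicate 2, and 16 and 12 erythroid genes.

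The fourth comparison asked which gene groups had distal open regions, the class that includes enhancers. Cardiac transcription factor genes had 20 distal regions in replicate 1 and 11 in replicate 2, 4.43 ± 0.586 times the random mean (SD, n = 2) and above 10000 and 9963 random lists, so the list was called high. Gata5 had 2 and 3 distal regions, Mef2d 2 in each, Tead1 and Myocd 2 and 1, and Gata6 and Mef2c 1 and 2. The strongest of the list shared by both replicates lay 9852 bp from a Mef2d TSS, on chromosome 3 from 88177463 to 88178308 (signal 11.1 ± 1.85, SD, n = 2). The call was lost in the pseudoreplicated lists, at 2.96 times random in replicate 1 and 1.59 in replicate 2 (mean 2.27), and in the top 50% of rows by −log10 q, at 3.46 times, and against unmatched lists the ratio was 7.36. Erythroid genes were called high too, with 8 and 6 distal regions, 8.06 ± 0.379 times random (SD, n = 2) and above 9998 and 9982 random lists. Hbb-y had 2 in each replicate, Tal1 2 and 1, and Spta1, Slc4a1 and Klf1, an erythroid transcription factor, 1 in each. Against unmatched lists the erythroid ratio was 4.33 and was not called, and in the pseudoreplicated lists it was 3.48 and still called.

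Sarcomere genes had 10 distal regions in replicate 1, above 9986 random lists, and 2 in replicate 2, above 5597. Myl3 had 2 and 1, Myl2 1 in each, Myh7 3 and 0, and Actn2 2 and 0. The list was not called, and without replicate 2 it would have been, at 4.49 times random against 1.25 without replicate 1. The strongest shared region lay 13098 bp from Myl3, on chromosome 9 from 110781237 to 110782111 (5.67 ± 0.941, SD, n = 2). Ion handling genes had 9 and 2 regions, among them Kcnh2 with 2 and 1, and were not called. Their strongest shared region lay 1118 bp from a Kcnh2 TSS, on chromosome 5 from 24352341 to 24352983 (4.64 ± 1.73). Endothelial genes had 6 regions in replicate 1 and 10 in replicate 2, the opposite order, above 8913 and 9979 random lists, which was not called. They were called high in the pseudoreplicated lists, at 2.28 times random against 3.55 in the thresholded lists. Nfatc1, an endocardial transcription factor, had 0 and 3, Tek 1 and 2, Flt1 2 and 0, and Sox17 and Vwf 1 in each. An intron of Vwf held the strongest of the endothelial regions shared by both replicates, on chromosome 6 from 125573251 to 125573598 (10.0 ± 1.49).

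Smooth muscle genes had 5 and 3 distal regions, of which Notch3 held 3 and 2, and were not called. The region 33360 bp from Notch3 lay on chromosome 17 from 32099702 to 32100568 (8.54 ± 0.0637, SD, n = 2). Fibroblast genes had 2 and 1, with a region 7267 bp from Col1a1 in both, on chromosome 11 from 94928739 to 94929262 (6.70 ± 2.90). Epicardial genes had 1 and 0, near Sema3d. Macrophage genes had 1 and 3, all near Fcgr3, neural genes 3 and 1, liver genes 1 and 1, skeletal muscle genes 1 and 0 and lung and foregut genes 2 and 1. Cell cycle genes had 3 and 2, and ubiquitous genes 5 and 4, among them 1 in each at Hprt, Ywhaz and Ubc. None of these lists was called, though in the conservative list ubiquitous genes were called high, at 5.44 times random. Olfactory receptor genes were called low, with 3 and 4 distal regions at 1135 genes.

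The fifth comparison asked which transcription factor motifs lay at distal summits more often than in their flanks. Motifs of CTCF, SP/KLF, ETS, AP-1, NFY and MEIS factors were more frequent in both replicates. CTCF, which binds at boundaries of chromatin loops, stood at 13.96 and 11.7 times the flanks (95% intervals 6.22 to 42.8 and 4.41 to 67.2). SP/KLF stood at 7.76 and 11.5 times, ETS at 5.04 and 4.20, AP-1 at 2.74 and 3.34, NFY at 2.13 and 2.14, and MEIS at 1.73 and 1.22. Against GC-matched random windows the mean SP/KLF ratio fell from 9.63 to 2.82 and was still called, while the calls of MEIS (1.31) and of CTCF (13.3, with an interval in 1 replicate only) were lost. ETS and MEF2 gave no ratio there, because no GC-matched window of replicate 2 held a match. Among 3467 summits and 3467 such windows of replicate 1, MEF2 matched 60 and 1 and ETS 39 and 2. Among 2293 of each in replicate 2, MEF2 matched 11 and 0 and ETS 27 and 0. In the top 50% of rows by −log10 q the calls of MEIS (1.58), ETS (6.85) and CTCF (13.7) were lost, and in the pseudoreplicated lists the SP/KLF ratio was 5.59 and that of NFY 1.26, both still called. MEF2, a factor family of muscle genes, stood at 5.82 times in replicate 1 (interval 3.62 to 9.44) and 2.15 times in replicate 2 (0.863 to 4.70), and was not called. The share of summits with a MEF2 match was 1.68% in replicate 1 and 0.466% in replicate 2. TEAD stood at 2.10 (1.60 to 2.76) and 1.33 (0.914 to 1.81) and SRF at 1.76 (1.29 to 2.40) and 1.06 (0.606 to 1.77), with the interval above 1 in replicate 1 only. Both MEF2 (3.71) and TEAD (1.69) were called higher in the pseudoreplicated lists. GATA, at 23.4% and 22.4% of summits, did not differ from the flanks, with ratios of 1.03 and 0.991.

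NKX2 (0.823 and 0.588), HAND/E-box (0.855 and 0.794) and FOX motifs (0.624 and 0.697) were less frequent at summits than in flanks. Against GC-matched random windows these lower calls were lost too and NKX2 and FOX turned, to 1.20 and 1.57 times, while GATA (2.06), TEAD (2.12) and POU/OCT (2.97) were called higher. In the pseudoreplicated lists the calls of NKX2 (0.944) and HAND/E-box (1.02) were lost and POU/OCT was called lower (0.658), and in the conservative list that of FOX (0.908) was lost. TBX, HNF4, SOX and POU/OCT motifs were not called, with mean ratios of 1.00, 1.21, 0.903 and 1.20. HNF1, NFI and REST motifs had at most 2 matches among the summits of a replicate and gave no ratio.

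**Figure D4:**
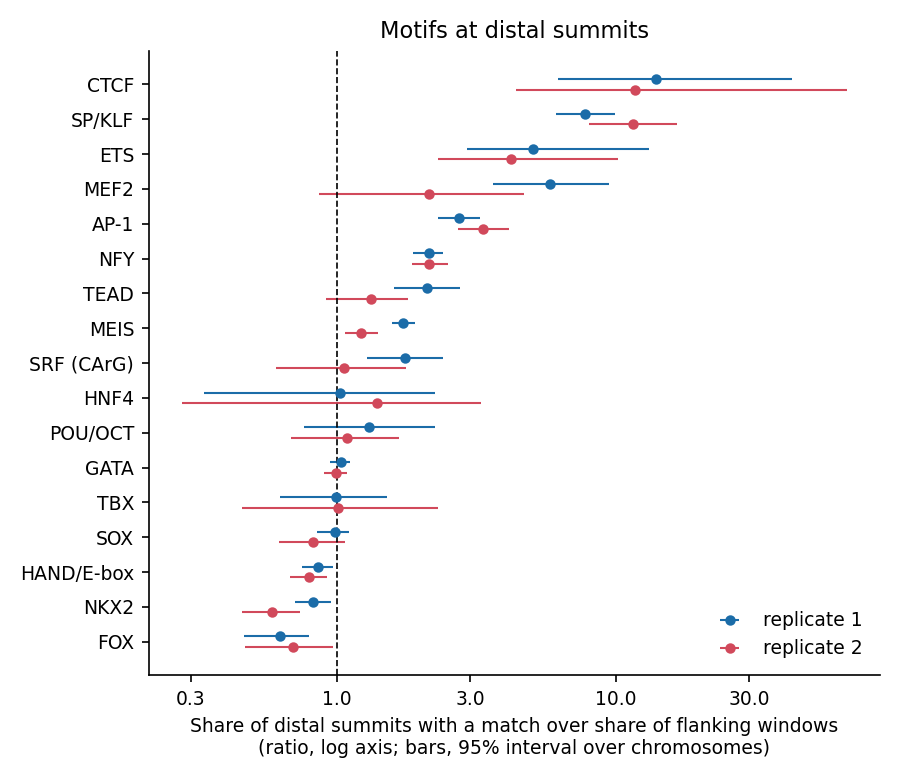
Ratio of the share of distal summits with a motif match to the share of flanking windows with one (horizontal log axis) for 17 motifs, with points for each replicate and bars for the 95% bootstrap interval over chromosomes. MEF2 lies at 5.82 in replicate 1 and 2.15 in replicate 2, and CTCF at 13.96 and 11.7.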

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

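The ranked lists held strong regions that the thresholded lists, on which the report rests, did not. The tests were set before the values they measure were seen, and the joining of intervals into loci and the baseline of distal regions were chosen after. In replicate 1, 165 summit rows in 71 intervals reached the thresholded lists' lowest score of 540 in the ranked list and were missing from the thresholded one. In replicate 2 there were 187 such rows in 94 intervals. They stand out because they are signal in data outside the comparisons, with no control library to set them against. Of these rows, 37 and 51 lay on contigs outside the 21 chromosomes. Among those on the 21 chromosomes, the highest by −log10 p in both replicates was on chromosome 1 from 24611587 to 24616165, at 2628 in replicate 1 and 2981 in replicate 2. The intervals from 103648978 to 103649356 of chromosome 6 (1171) and from 98666172 to 98667350 of chromosome 2 (1003) followed in replicate 1.

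The missing intervals may be sequence that resembles mitochondrial DNA or that is present in several copies, both of which collect reads without being open chromatin. Of the 68 loci on chromosomes, with overlapping intervals of both replicates joined, 1.47% (1 locus) had over 50% of their 16-base words in the mitochondrial genome, which argues against mitochondrial sequence for the set. The 1 exception was the interval on chromosome 1, with 99.5% of its words. For copies, the median share of 31-base words found elsewhere on the chromosomes was 27.1% over these loci, against 0% in 300 regions sampled from those kept in each replicate and 0% in 300 distal ones, but it stayed under the 50% set beforehand, so this explanation stays open. What the authors' further file removed was not tested, and no biological explanation was tested because the design holds 1 group.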

How the results depend on the processing

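The 57 results were recomputed under 441 alternatives, of which 357 kept their call, stayed within the spread of the replicates or, for the mean number of regions, within 1.5 times the value. A result not called that changed direction without being called counts among these, as in 37 cases of gene lists and motifs. In the other cases the cause was not tested. No paired analysis was possible because the samples form 1 group. HNF1, NFI and REST gave no motif ratio for lack of matches and were not recomputed, MEF2 and ETS gave none against GC-matched windows because no window of replicate 2 held a match, and depth could not be varied because the lists hold no reads. The restriction of motifs to shared distal regions and the use of outermost 5′ ends were chosen after seeing the data.

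In the pseudoreplicated lists the mean number of regions rose to 26789, sharing fell to 42.5% of replicate 1 and 59.0% of replicate 2 regions, rho was 0.815 and the promoter share 57.1%. Promoters of endothelial (1.24), fibroblast (1.03) and smooth muscle genes (1.37) turned to above random without a call, and distal erythroid regions fell to 3.48 and kept theirs. The epicardial promoter call (0.603 times random, through replicate 1) and the distal call of cardiac transcription factors (2.27) were lost there, distal endothelial regions were called high (2.28), MEF2 (3.71) and TEAD (1.69) motifs were called higher, the NKX2 call was lost (0.944), HAND/E-box turned (1.02) and POU/OCT turned to lower (0.658). With the top 50% of rows by −log10 q, the mean number of regions fell from 10786 to 7672, sharing was 70.4% and 95.1%, rho 0.713 and the promoter share 89.4%. Endothelial promoters were then called low (0.145) and ubiquitous ones high (1.63), while calls were lost for olfactory receptor promoters (0.129), distal cardiac transcription factors (3.46) and the motifs MEIS (1.58), ETS (6.85), CTCF (13.7) and FOX (0.663). For ETS and CTCF an interval could not be formed there from the few matches in flanks. Sharing was 64.9% and 73.1% with a reciprocal overlap of 50%, and 77.6% and 81.3% with equal numbers of top regions. The rho of −log10 p was 0.829. The promoter share was 80.0% within 500 bp, 80.7% with 1 summit per region and 86.98% in the conservative list.

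Against unmatched random lists, erythroid calls were lost at promoters (1.15) and distal regions (4.33), sarcomere promoters turned to 0.935 without a call, while macrophage (0.153) and liver (0.122) promoters were called low and cell cycle (2.22) and ubiquitous (2.19) ones high. With outermost 5′ ends, cell cycle promoters were called high (1.45) and smooth muscle promoters fell from 0.904 to 0.240 without a call. In the conservative list, distal regions of ubiquitous genes (5.44) and the motifs MEF2 (4.37) and TEAD (1.44) were called high and FOX lost its call (0.908). Against GC-matched windows, GATA (2.06), TEAD (2.12) and POU/OCT (2.97) were called higher, SP/KLF fell to 2.82 and kept its call, NKX2 (1.20) and FOX (1.57) turned, and HAND/E-box (0.916), MEIS (1.31) and CTCF (13.3) lost their calls. With windows of 50 bp, NKX2 (0.736) and HAND/E-box (0.823) lost theirs. At shared distal regions, HAND/E-box (0.781), CTCF (11.9) and FOX (0.606) lost theirs and SOX was called lower (0.755). In both of the last CTCF cases an interval could not be formed in 1 replicate.

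Some calls came with 1 replicate alone that both did not give. Leaving out 1 replicate, promoter ratios ranged from 0.840 to 2.71 for sarcomere, 0.374 to 0.421 for endothelium, 0.412 to 0.462 for fibroblast, 0.520 to 1.29 for smooth muscle (not called), 1.26 to 1.39 for cell cycle and 1.35 to 1.37 for ubiquitous genes. Distal ratios ranged from 1.25 to 4.49 for sarcomere and 2.09 to 5.02 for endothelial genes. Motif ratios ranged from 2.15 to 5.82 for MEF2, 1.33 to 2.10 for TEAD and 1.06 to 1.76 for SRF. The calls for sarcomere genes, promoters of endothelial, fibroblast and ubiquitous genes, MEF2, TEAD and SRF came with replicate 1 alone, and those for cell cycle promoters and distal endothelial regions with replicate 2 alone.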

Other observations

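The tests on signal ratios of gene lists and the comparison of copies in the strongest distal regions with other distal regions were chosen after the values were seen, as were the families of genes, and the other tests before. Families of genes outside the lists, grouped by symbol, differed in promoter accessibility. Homeobox genes of the Hox clusters, which pattern the body axis, were open in 0 of 39 cases in replicate 1 and 1 in replicate 2, against 59.0% in CpG-matched random lists and below 10000 of 10000 of them in both. Keratin genes, which encode intermediate filaments of epithelia, were open in 1 and 0 of 49 cases, below 9985 and 9995 lists. Genes of cytosolic ribosomal proteins were open in 67 and 64 of 76 cases, above 9981 and 9995 lists. Zfp genes, zinc finger proteins of which many are transcriptional repressors, were open in 236 and 202 of 365 cases, above 10000 lists in both. Mitochondrial ribosomal protein genes (59 and 51 of 75), proteasome subunit genes (30 and 31 of 39) and complex I subunit genes (28 and 27 of 36) did not stand above 9900 lists in both. Clustered histone genes were open in 44 and 34 of 67 cases, below 9595 and 9996 lists, solute carriers in 148 and 136 of 371, below 9981 and 9720, and vomeronasal receptors in 1 and 1 of 327, below 7832 and 7115 lists, where 0.749% were open in random lists.

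In the longer pseudoreplicated lists, genes of several heart cell types were listed that the thresholded lists lacked, but epicardial, fibroblast and endothelial genes were not called there against random lists of like CpG content. Epicardial genes were listed in 8 of 12 cases in replicate 1, among them Wt1 and Tbx18, at 1.21 times random, and in 0 in replicate 2. Fibroblast and valve genes were listed in 12 and 7 of 17 cases (1.19 and 0.860 times random), with Postn in replicate 1 only. Endothelial genes were listed in 15 and 10 of 21 cases (1.37 and 1.12 times), with Kdr at a signal of 7.18 and 6.87. Of the sarcomere genes, Tnnt2 (8.39), Tnni1 (9.64), Ttn (8.47) and Actc1 (7.11) were listed in replicate 1 and absent from replicate 2. Of those listed in both, Tpm1 (7.31 and 7.73) and Myom1 (9.26 and 10.28) had close signals. In the thresholded lists the Myom1 region also lay at a TSS of Myl12a and Myl12b. At genes listed in both replicates, the median ratio of signal in replicate 2 to replicate 1 was 0.640 over 7 sarcomere genes, below 9194 of 10000 sets matched on replicate 1 signal, and 0.569 over 7 fibroblast and valve genes, below 9978. It was 0.758 over 11 erythroid and 0.882 over 8 endothelial genes, against 0.761 over all genes. Cell cycle genes were listed in 22 and 20 of 22 cases and ubiquitous genes in 20 and 19 of 20.

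Sarcomere promoters open in replicate 1 were mostly absent from replicate 2, with 4 of 15 (26.7%) found there against 84.5% of all 9488 genes open in replicate 1. Without the Myl4 and Myom1 regions, which also lay at other genes, 2 of 13 were found there. Lower depth or signal in replicate 2 is argued against as the whole cause, since genes of like −log10 p in replicate 1 kept 11.7 of 15 on average and 10000 of 10000 random sets kept more. A different recovery of promoters of low CpG content (observed over expected) is argued against likewise, with 9996 of 10000 sets of like CpG content keeping more. GC content itself was not matched, so a difference in its recovery between the libraries was not tested. More blood cells in replicate 2 may have lowered the share of other cells, which stays open. The ratio at erythroid promoters (0.758) lay above only 3123 of 10000 matched sets. For other cells it was 0.569 at fibroblast, 0.882 at endothelial, 0.796 at cardiac transcription factor and 0.771 at ion handling genes, against 0.761 over all genes. These ratios cover only genes listed in both pseudoreplicated lists, so genes missing from replicate 2 do not enter them. Listed genes were fewer in replicate 2 in every heart list, among them epicardial (8 and 0), smooth muscle (7 and 3) and endothelial genes (15 and 10). Erythroid genes were fewer there too (16 and 12). The ratios therefore cannot tell whether other cells moved together. Another dissection was not tested, and a mislabelled sample stays open. Replicate 2 by itself had distal regions at cardiac transcription factor genes above 9963 random lists and 0 of 19 neural genes open. Those 11 distal regions came from 6 genes. The rank fell to 9672 in the pseudoreplicated list and to 7877, with 2 regions, in the top 50% of rows by −log10 q. Promoters of replicate 2 at cardiac transcription factor genes, 13 open with Nkx2-5 (5.36) and Tbx20 (7.39) among them, stood at only 0.946 times random. Of the regions of replicate 2, 85.4% were shared with replicate 1, but 8386 of the 10150 were promoter regions. Those were shared at 90.9% and intron regions, of lower median signal (5.17 against 7.75), at 50.5%. No other tissue was there to set this sharing against. With 1 group, no biological explanation other than more blood cells was tested.

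The 10 strongest distal regions, picked for strong signal in both replicates, included 4 that lay 831186 to 1765843 bp from the nearest TSS of a protein-coding gene. Mitochondrial sequence may account for part of them, as 4 of the 10 had over 50% of their 16-base words in the mitochondrial genome and 7 had 45.4 to 70.5%. Of 300 other distal regions sampled from each replicate, 0 and 2 had over 50%. The 3 near Pak3, Frmd4a and Myl12b had none, which argues against it for these 3. For the other 7 it stays open, as the source of their reads was not tested. Over 10% of such words were found in 13 of 11422 regions of replicate 1, of which 13 were distal and 13 shared, and in 14 of 10150 regions of replicate 2, of which 13 were distal and 13 shared. The median signal percentile of such regions was 99.9 in replicate 1 and 92.1 in replicate 2. Copies of the sequence on the chromosomes may account for part of the 10 strongest too, although 1 of the 10, the region 1765843 bp from G6pd2, had over 50% of its 31-base words elsewhere, a count set beforehand as speaking against copies. That bound passed over partial copies, since the median share was 32.6% against 0% in 300 other distal regions sampled from each replicate, above 9999 and 10000 of 10000 random draws of 10 from them, so this stays open as well, and with 1 group no biological explanation was tested.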
